A study of Mus musculus with 8 samples.

How the data were processed

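RNA sequencing was deposited for 8 mouse brain libraries, 4 named Ctrl and 4 named Ep1. Per the labels, total RNA was extracted with Trizol and sequenced on an Illumina instrument. The expression values are FPKM as deposited, fragments per kilobase of the length given in the table, scaled by 1 total per library. The submitters' processing notes name Bowtie 0.12.2 and the genome build mm8 without a role, while the gene coordinates in the table matched GRCm38: of 55227 identifiers found in GENCODE M21, 99.4% had the same start and end. The counting tool, strandedness and filters were not stated, so antisense and overlapping transcripts were not separated here.

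The table held 55780 genes, of which 22561 were 0 in all libraries and 293 carried identifiers of unannotated loci. The 8 columns, named by letter and number, were assigned to Ctrl 1 to 4 and Ep1 1 to 4 by those letters and numbers, which is an inference. No per-sample column was left unused. FPKM multiplied by length was a whole multiple of 1 value per library, to within 0.01 for 100% of genes checked, which gave 15038147 to 17772972 fragments per library. No batch was labelled and no comparison by the authors was used here.

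Genes with a mean of at least 1 FPKM in either group were tested, 14710 in all, as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trended and robust empirical Bayes variance. Values were adjusted with Benjamini-Hochberg at 0.05. Ep1 was compared with Ctrl, and a fit with 3 groups compared each energy with Ctrl and the energies with each other. In total 28 gene lists and 14 marker lists, each named with its result below, were tested with camera in limma at a preset inter-gene correlation of 0.01. Camera was repeated with the correlation estimated, and fry was run as well. The 39 lists with at least 5 tested members entered the tests. Genes below 1 FPKM in 1 group entered only through the other group, which favours changes in lists with many low genes. Each list was also adjusted over the list alone. Tables were prepared in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

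Comparisons, lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 called genes with an annotated symbol, no overlap between groups and the largest change in each direction. It added up to 3 members of each list with the smallest p, and 15 endothelial and stress genes whatever their result. For the energies it took 5 genes in each direction, or the 5 with the smallest p where fewer passed. Other genes are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

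The pipeline was tested on simulated data with 14443 genes, 200 of them changed. It recovered 77.8% of genes changed by a factor of 1.5, 87.9% at a factor of 2 and 95.2% at a factor of 4. Of 181 calls 14 were false, or 7.73%. The 1 raised list was called and 0 of the other lists were. Genes were drawn independently in the simulation, so false calls of camera among correlated genes were not tested. Far fewer genes were changed in it than were called in the real data. Alternatives changed the pseudocount, the filter, the scaling, the variance model, the threshold, the gene set, the grouping and each replicate in turn. Voom weights on recovered fragments, removal of GC and length trends, and removal of mitochondrial genes with CT010467.1 were added after the data were seen.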

Results

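RNA sequencing profiles were obtained from C57BL/6 mouse brain tissue in 8 libraries, 4 named Ctrl and 4 named Ep1. The labels describe Ctrl as untreated and Ep1 as treated with PDT, with 10 J/cm2 for Ep1 1 and 2 and 20 J/cm2 for Ep1 3 and 4. The series title speaks of MNP treatment and its design text of magnetic force, so the nature of the treatment was not settled by the labels, and Ep1 is used below as a group name. The labels name both brain tissue and brain microvessel endothelial cells. Camk2a of neurons and Mbp of oligodendrocytes were far more abundant than Cldn5 and Pecam1 of endothelial cells. In Ctrl, Camk2a stood at 442 ± 18.4 FPKM (SD, n = 4) and Mbp at 312 ± 62.0, against 21.1 ± 3.51 for Cldn5 and 2.51 ± 0.304 for Pecam1. Not every marker followed: the oligodendrocyte marker Ermn lay below the endothelial marker Itm2a in every Ctrl library. Camk2a and Mbp, Ermn and Itm2a in this contrast, and Wfs1 below were chosen after their values were seen. Between 15038147 and 17772972 fragments per library lay behind the values. No label stated that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical.

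Libraries differed first by group. The first principal component held 50.8% of the variance and placed all 4 Ctrl libraries on one side and all 4 Ep1 libraries on the other, with Ep1 2 nearest to Ctrl. Pearson correlation across genes, which are not independent replicates, ran from 0.979 to 0.986 within Ep1 and from 0.936 to 0.978 between groups. Ctrl 3 stood apart from the other controls, with r between 0.967 and 0.971 against 0.986 to 0.988 among the rest, and mitochondrial transcripts took 5.08% of its fragments against 3.24% to 3.50% in the other 3 controls. Each library was counted as 1 sample.

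**Figure D1:**
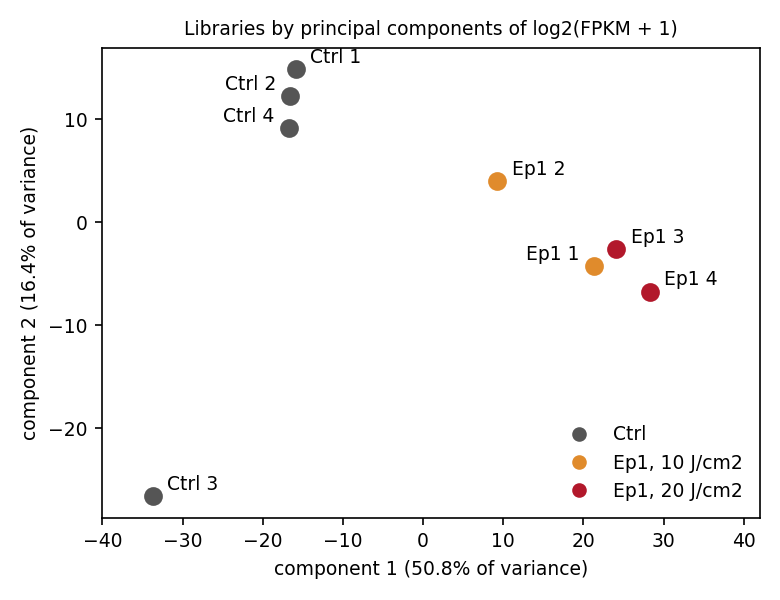
Principal components 1 and 2 of log2(FPKM + 1) over 14710 genes, 1 point per library, with the share of variance on each axis in percent (50.8% and 16.4%). Ctrl libraries lie at negative and Ep1 libraries at positive values of component 1, and Ctrl 3 lies apart from the other controls on both components.

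The comparison of Ep1 with Ctrl asked which transcripts differed between treated and untreated brain. Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, rose from 2.39 ± 0.320 FPKM in Ctrl to 22.8 ± 5.26 in Ep1 (SD, n = 4 each, log2 change 2.79 ± 0.15 SE, limma adjusted p = 4.85e-05). Nptx2, a secreted pentraxin of excitatory synapses, rose from 15.1 ± 1.34 to 112 ± 26.5 FPKM, and Cdkn1a, an inhibitor of cyclin-dependent kinases, from 2.64 ± 0.583 to 23.9 ± 5.06. The chemokine gene Ccl4, the heat shock gene Hspa1b, Ctla2a, Tubb6, the lipopolysaccharide co-receptor gene Cd14 and the globin genes Hba-a1 and Hbb-bs completed the 10 named genes with the largest rises. Among genes that fell, Drd2, the dopamine D2 receptor, went from 6.90 ± 0.702 to 1.34 ± 0.939 FPKM, Adora2a, an adenosine receptor, from 9.43 ± 1.21 to 2.28 ± 1.05, and Gkn3 from 5.71 ± 0.719 to 0.872 ± 0.261. Syndig1l, Gpr6, Slco1a4, P2ry12, Slc22a8, Gpr52 and the microRNA gene Mir208a made up the rest of the 10 largest falls. Each of these 20 genes had all 4 Ep1 values on one side of all 4 Ctrl values, which the rule for naming genes required. In GRCm38, Hmox1 (ENSMUSG00000005413) lies on chromosome 8 at 75093621 to 75100589 and Drd2 (ENSMUSG00000032259) on chromosome 9 at 49340627 to 49408177.

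In all, 3841 of 14710 tested genes passed an adjusted p of 0.05 in limma, 2275 higher and 1566 lower in Ep1. Of these, 203 higher and 36 lower genes changed by at least 1 on the log2(FPKM + 1) scale, which understates the change of low genes. The groups did not overlap for 31.8% of genes, where chance gives 2.86%. Without Ctrl 3 the count was 3902, and without Ep1 4 it was 2427. The balance of directions depended on scaling. With mitochondrial genes and CT010467.1 left out and the rest set to one sum, 1950 genes were higher and 2028 lower. The call of Mir208a, a short gene, was lost in several settings, including without Ctrl 3 (adjusted p = 0.0813). Hba-a1, Hbb-bs, Hspa1b and Ccl4 have close copies in the genome, and reads shared between copies leave their single values uncertain.

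Junction and transporter genes known from the brain endothelium moved in both directions. Each value covers all cells of a sample, so it does not show which cell type changed or whether cell shares did. Cdh5, the cadherin of endothelial adherens junctions, rose from 3.07 ± 0.214 to 10.5 ± 2.97 FPKM (n = 4 each, limma adjusted p = 0.000754). Pecam1 rose from 2.51 ± 0.304 to 6.07 ± 1.03 FPKM. Cldn5, the main claudin of the blood-brain barrier, rose from 21.1 ± 3.51 to 32.9 ± 6.18 FPKM (limma adjusted p = 0.0205). The glucose transporter gene Slc2a1 rose from 28.7 ± 2.36 to 45.9 ± 7.21 FPKM and the lipid transporter gene Mfsd2a from 9.28 ± 0.548 to 15 ± 1.13. Other transporter genes fell. Abcb1a went from 6.31 ± 0.242 to 3.79 ± 0.283 FPKM, Slco1a4 from 10.3 ± 0.465 to 2.89 ± 0.853 and Slc22a8 from 7.40 ± 0.557 to 2.10 ± 0.429. Tjp1 (15 ± 0.548 and 15.6 ± 1.33 FPKM in Ctrl and Ep1), Ocln (2.12 ± 0.226 and 1.75 ± 0.391), Plvap (6.89 ± 1.84 and 8.69 ± 0.693), Cav1 (3.44 ± 0.326 and 4.28 ± 0.745), Klf2 (4.88 ± 1.22 and 4.50 ± 0.571) and Fth1 (316 ± 32.1 and 372 ± 28) did not pass. In single alternatives Plvap passed without Ctrl 1 (adjusted p = 0.0317), Cav1 with GC and length trends removed (adjusted p = 0.0299) and Fth1 with voom (adjusted p = 0.0432). Cldn5 (ENSMUSG00000041378) lies on chromosome 16 at 18776847 to 18778262. Piezo1, a mechanically gated channel, rose from 1.25 ± 0.0967 to 2.89 ± 0.937 FPKM and Klf4 from 1.12 ± 0.170 to 2.15 ± 0.284.

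Of 25 tested tight junction and adherens junction genes, 7 rose and 4 fell (7 and 5 adjusted over the list alone), with no shift of the list relative to other genes past the threshold (camera adjusted p = 0.600). Of 24 blood-brain barrier transporter genes, 8 rose and 8 fell (9 and 8 adjusted over the list alone, camera adjusted p = 0.746). The endothelial cell markers likewise split, 10 rising and 6 falling of 22 (11 and 6 adjusted over the list alone, camera adjusted p = 0.277). Adgrl4 rose from 2.38 ± 0.173 to 6.08 ± 0.746 FPKM, while Itm2a fell from 25.8 ± 1.58 to 10.9 ± 0.862. Among 25 caveolae, transcytosis and endocytosis genes 10 rose and none fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.000593, and adjusted p = 0.439 with an estimated correlation). Cavin1 led, from 4.66 ± 0.614 to 15 ± 3.15 FPKM. In the angiogenesis, VEGF and Notch list 9 of 26 rose and 4 fell (11 and 5 adjusted over the list alone, camera adjusted p = 0.0516), and that list passed without any 1 of Ctrl 1, Ctrl 4 and Ep1 2 (smallest adjusted p = 0.0290), with replicate numbers as a block (adjusted p = 0.0342), with quantile normalization (adjusted p = 0.0203) and by fry (adjusted p = 0.00612). There Angpt2 rose from 0.489 ± 0.192 to 4.08 ± 0.982 FPKM and its receptor gene Tek fell from 2.53 ± 0.244 to 1.04 ± 0.162. For Wnt/beta-catenin signalling in brain endothelium 3 of 20 rose and 2 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.600). The call of Cldn5 was lost without Ep1 3 (adjusted p = 0.0584), without Ep1 4 (adjusted p = 0.0610), with no filter on low values (adjusted p = 0.0506) and with replicate numbers as a block (adjusted p = 0.0655). Ctrl 3 had the lowest Cldn5 value of the 8 libraries.

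**Figure D2:**
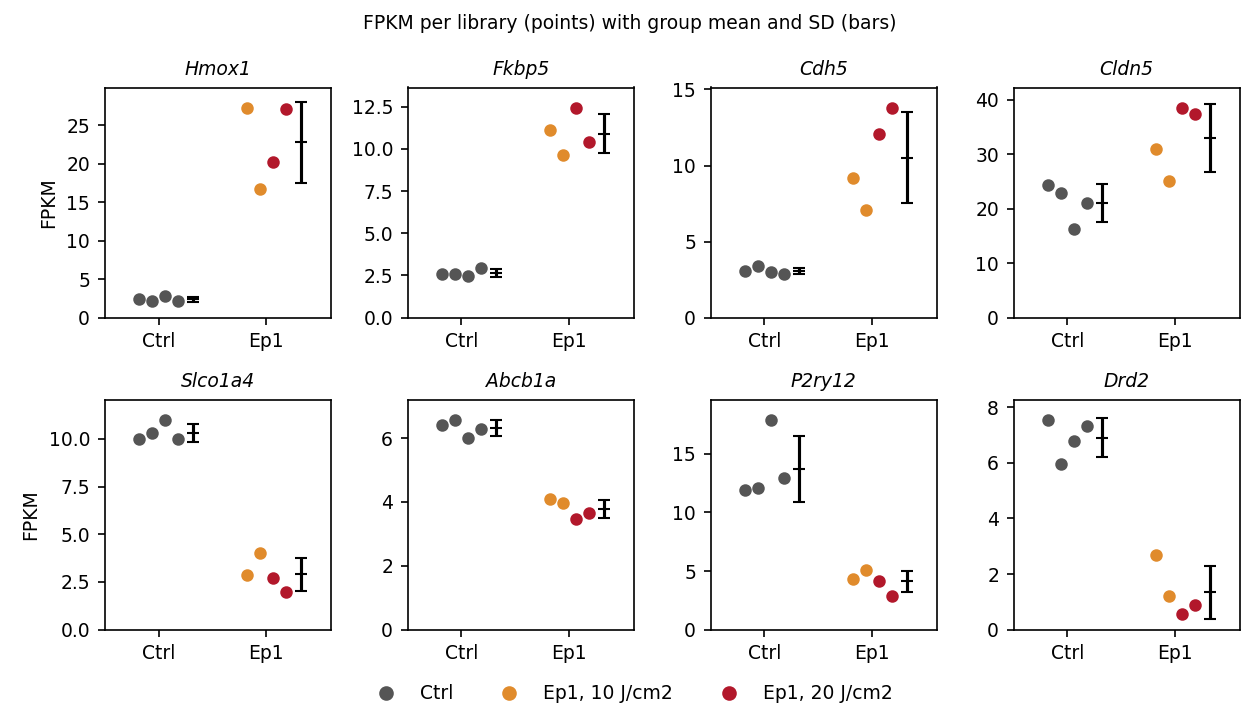
FPKM (linear axes from 0) of 8 named genes in each library, with points coloured by group and energy and bars giving the mean and SD of the 4 libraries of a group. Hmox1, Fkbp5, Cdh5 and Cldn5 lie higher and Slco1a4, Abcb1a, P2ry12 and Drd2 lower in all 4 Ep1 libraries than in all 4 Ctrl libraries.

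Of 17 glucocorticoid response genes 16 rose and none fell (16 and 0 adjusted over the list alone), with a median log2 change of 0.78 (camera adjusted p = 2.57e-10, and adjusted p = 0.439 with an estimated correlation). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 2.65 ± 0.222 to 10.9 ± 1.16 FPKM and Plin4 from 0.625 ± 0.224 to 5.21 ± 1.16. In the NF-kB and cytokine list 17 of 20 rose (17 adjusted over the list alone) with a median of 0.85 (camera adjusted p = 8.27e-09, and adjusted p = 0.439 with an estimated correlation). Ccl3 went from 0.0932 ± 0.0713 to 4.45 ± 0.932 FPKM and Lcn2 from 0.0561 ± 0.0394 to 2.31 ± 0.225. Only 20 of the 32 genes in this list were tested. Members low in Ctrl, such as Ccl3 and Lcn2, entered only through their Ep1 values. That favours rises in the count, the median and the camera result. The chemokine gene Cxcl12 was the 1 member that fell (2 adjusted over the list alone), from 7.51 ± 0.382 to 3.81 ± 0.239. Of 30 immediate early genes 17 rose and 1 fell (20 and 1 adjusted over the list alone, median 0.68, camera adjusted p = 2.92e-05, and adjusted p = 0.538 with an estimated correlation), with Egr3 at 27.6 ± 2.25 FPKM in Ctrl and 80.5 ± 19.2 in Ep1. Interferon-stimulated genes (3 of 16 rose and none fell, also when adjusted over the list alone, camera adjusted p = 0.668) did not shift past the threshold as a list. Neither did MHC class I and antigen presentation genes (2 of 11 rose and none fell, also when adjusted over the list alone, camera adjusted p = 0.0898). That list also holds class II genes. The interferon-stimulated genes Irf1 and Ifitm3 lost their calls without Ep1 3 (adjusted p = 0.0639 and 0.0635) and without Ep1 4 (adjusted p = 0.0657 and 0.0651). Irf1 also lost its call without Ctrl 1 (adjusted p = 0.0557), and Ifitm3 without any 1 of Ctrl 3, Ctrl 4 and Ep1 1 (largest adjusted p = 0.0622) and without the filter on low values (adjusted p = 0.0584). With replicate numbers as a block Ifitm3 and Gbp2 lost theirs (adjusted p = 0.0507 and 0.0539). Without Ctrl 3 the list had 3 rising and 1 falling of 15. Without Ctrl 3 the count of the MHC class I and antigen presentation list was 0. Its 2 members, H2-D1 and H2-K1, each also lost their call without any 1 of Ctrl 2, Ctrl 4, Ep1 3 and Ep1 4 (largest adjusted p = 0.101), H2-D1 also without Ep1 1 (adjusted p = 0.0603) and H2-K1 also without Ctrl 1 (adjusted p = 0.0924). The MHC class I and antigen presentation list passed without Ep1 1 (camera adjusted p = 0.0434).

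For heat shock genes 8 of 22 rose and none fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.00197, and adjusted p = 0.439 with an estimated correlation), with Hspa1b at 2.23 ± 0.380 FPKM in Ctrl and 19.4 ± 7.48 in Ep1. For the unfolded protein response 15 of 25 rose and none fell (15 and 0 adjusted over the list alone, camera adjusted p = 0.000159, and adjusted p = 0.439 with an estimated correlation), with Atf3 at 0.178 ± 0.130 and 3.88 ± 1.76. Actin cytoskeleton and stress fibre genes rose in 18 of 35 cases and fell in none (22 and 0 adjusted over the list alone, camera adjusted p = 6.76e-06, and adjusted p = 0.439 with an estimated correlation), Ezr going from 19.3 ± 1.75 to 39.2 ± 2.27 FPKM. Of 23 mechanosensing and shear response genes 13 rose and 2 fell (16 and 2 adjusted over the list alone, camera adjusted p = 0.000107, and adjusted p = 0.455 with an estimated correlation). Hypoxia and glycolysis genes rose in 16 of 29 cases and fell in none (17 and 1 adjusted over the list alone, camera adjusted p = 1.83e-05, and adjusted p = 0.439 with an estimated correlation), with Adm at 0.631 ± 0.0846 and 7.56 ± 3.01 FPKM. Cholesterol biosynthesis genes rose in 13 of 23 cases and fell in none (16 and 1 adjusted over the list alone, camera adjusted p = 6.48e-05, and adjusted p = 0.439 with an estimated correlation), with Mvd at 9.94 ± 1.52 and 24.2 ± 3.52. Extracellular matrix and basement membrane genes rose in 10 of 27 cases and fell in none (10 and 1 adjusted over the list alone, camera adjusted p = 0.00197, and adjusted p = 0.528 with an estimated correlation), with Col4a1 at 7.85 ± 0.657 and 20.1 ± 3.87.

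Other lists did not shift past the threshold in camera with the preset correlation and all libraries. Of 26 Nrf2 target genes 5 rose and none fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.155), and of 20 iron handling and ferroptosis genes 5 rose and none fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.0898), which passed with GC and length trends removed (adjusted p = 0.0257). Hmox1 led both. For p53 targets and apoptosis 8 of 22 rose and 1 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.0913), and for YAP and TAZ targets 5 of 20 rose and none fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0774), which passed without Ctrl 1 (adjusted p = 0.0432). Lysosome and autophagy genes split into 4 rising and 3 falling of 32 (4 and 1 adjusted over the list alone, camera adjusted p = 0.902), and cell cycle genes into 2 rising and none falling of 9 (2 and 0 adjusted over the list alone, camera adjusted p = 0.560). Among 17 circadian clock genes 5 rose and 6 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.668), Cry1 from 5.85 ± 0.601 to 11.3 ± 1.91 FPKM and Nr1d2 from 27.9 ± 1.23 to 18.8 ± 1.17. Nuclear-encoded oxidative phosphorylation genes (0 of 41, camera adjusted p = 0.600) and mitochondrially encoded genes (0 of 13, camera adjusted p = 0.507) had no member past the threshold in limma, over all genes or adjusted over the list alone. In alternatives mt-Atp8 passed upward without Ep1 1 (adjusted p = 0.0328), with replicate numbers as a block (adjusted p = 0.0117) and with GC and length trends removed (adjusted p = 0.0123). Ndufs8 passed downward with quantile normalization (adjusted p = 0.0274), with those trends removed (adjusted p = 0.0199) and without mitochondrial genes and CT010467.1 (adjusted p = 0.0410). Of 63 cytosolic ribosomal protein genes 1 rose (0 adjusted over the list alone, camera adjusted p = 0.0895), and the list passed without Ctrl 4 (adjusted p = 0.0296) or Ep1 2 (adjusted p = 0.0359). Synaptic vesicle and neurotransmission genes split into 3 rising and 5 falling of 30 (3 and 5 adjusted over the list alone, camera adjusted p = 0.783). By fry the Nrf2 target (adjusted p = 0.0169), iron handling (adjusted p = 0.00338) and p53 lists (adjusted p = 0.00154) passed. The YAP and TAZ (fry adjusted p = 0.00912) and cell cycle lists (fry adjusted p = 0.0169) passed as well.

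Markers of single cell types and regions moved unevenly. Of 6 red blood cell markers 4 rose and none fell (5 and 0 adjusted over the list alone, median log2 change 1.88, camera adjusted p = 0.00197, and adjusted p = 0.439 with an estimated correlation). Hbb-bs rose from 12 ± 2.30 to 73.3 ± 35.4 FPKM. Among 15 microglia and macrophage markers 6 fell and 4 rose (6 and 4 adjusted over the list alone, camera adjusted p = 0.386). By fry these markers passed downward as a list (adjusted p = 0.0177). P2ry12 fell from 13.7 ± 2.81 to 4.11 ± 0.897 FPKM and Cx3cr1 from 8.97 ± 0.154 to 6.33 ± 0.329. That list had a median of 0.11 and a mean of -0.07. Gfap, the intermediate filament of astrocytes, rose from 31.7 ± 8.60 to 70.9 ± 7.97 FPKM, while the astrocyte list gave 6 rising and 1 falling of 15 (6 and 3 adjusted over the list alone, camera adjusted p = 0.245). The astrocyte list passed upward by fry (adjusted p = 0.0214). Pericyte markers fell in 4 of 10 cases and rose in none (4 and 0 adjusted over the list alone, camera adjusted p = 0.0496, and adjusted p = 0.439 with an estimated correlation), with Rgs5 at 22.4 ± 0.923 and 17 ± 0.422 FPKM. The list's call was lost without any 1 of Ctrl 1, Ctrl 2, Ep1 1 and Ep1 3 (largest adjusted p = 0.127), with replicate numbers as a block (adjusted p = 0.0532), with a pseudocount of 0.1 (adjusted p = 0.0509) and with quantile normalization (adjusted p = 0.0762). Region markers fell in 6 of 11 cases and rose in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0108, and adjusted p = 0.439 with an estimated correlation). Drd2 and Adora2a were among those that fell. The member that rose was Wfs1, from 30.0 ± 3.21 to 43.2 ± 3.41 FPKM.

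Among oligodendrocyte markers 5 of 14 fell and none rose (5 and 0 adjusted over the list alone, camera adjusted p = 0.0511), with Ugt8a at 18.5 ± 1.56 and 11.5 ± 1.11 FPKM. The list passed without any 1 of Ctrl 3, Ctrl 4 and Ep1 3 (smallest adjusted p = 0.00360), with replicate numbers as a block (adjusted p = 0.0461) and with quantile normalization (adjusted p = 0.0393). Oligodendrocyte precursor markers fell in 2 of 11 cases (2 adjusted over the list alone, camera adjusted p = 0.369), and without Ctrl 3 in 4, where the list passed (adjusted p = 0.0216), as it did with all libraries and GC and length trends removed (adjusted p = 0.0311). Neuron markers rose in 1 and fell in 1 of 17 (0 and 0 adjusted over the list alone, camera adjusted p = 0.668). Fibroblast and meningeal markers rose in 3 and fell in 2 of 13 (3 and 3 adjusted over the list alone, camera adjusted p = 0.735). Of 12 choroid plexus and ependyma markers 1 fell (1 adjusted over the list alone, camera adjusted p = 0.0511). That list passed without any 1 of Ctrl 3, Ctrl 4, Ep1 1 and Ep1 2 (smallest adjusted p = 0.00905), and with replicate numbers as a block (adjusted p = 0.00412). Smooth muscle markers (1 of 2 tested rose, 2 adjusted over the list alone), neutrophil markers (1 rose and 1 fell of 3, also when adjusted over the list alone) and lymphocyte markers (1 of 2 fell, 2 adjusted over the list alone) were too few for a list test. Of 39 lists tested 12 passed upward and 2 downward with the preset correlation, and none of the 14 calls held with an estimated correlation. There the smallest adjusted p was 0.439 and 3 lists had an unadjusted p under 0.05. The test fry, which asks only whether a list's own genes move one way, gave 22.

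**Figure D3:**
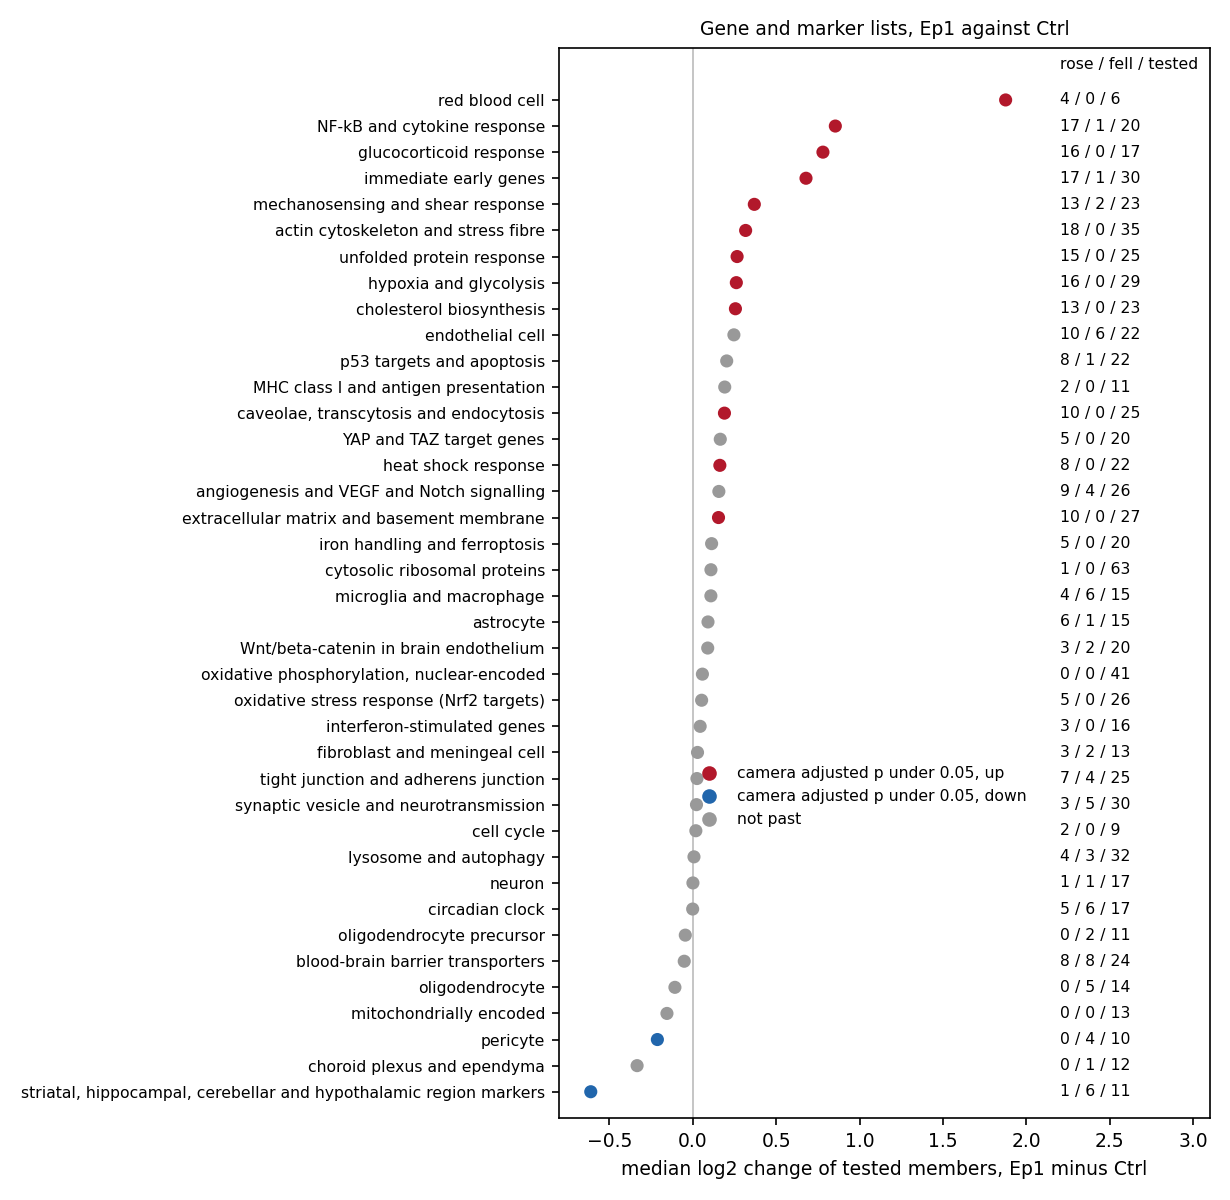
Median log2 change (Ep1 minus Ctrl, log2(FPKM + 1)) of the tested members of 39 gene and marker lists, 1 point per list, coloured by the camera call with a preset correlation of 0.01; the numbers at the right give members that rose, members that fell and members tested. The red blood cell list has the highest median, 1.88, and the region marker list the lowest, -0.61.

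By energy, the libraries labelled 10 J/cm2 were set against Ctrl. Hmox1 rose to a mean of 21.9 FPKM (n = 2; log2 change 2.72 ± 0.19 SE; limma adjusted p = 0.000931), Nptx2 to 108, Cdkn1a to 21, Ccl4 to 4.83 and Ctla2a to 10.9, and these were the 5 largest rises. The 5 largest falls were those of Adora2a, to 2.28 FPKM (log2 change -1.77 ± 0.29; adjusted p = 0.0134), Gkn3, Drd2, Syndig1l and Gpr6. In all 1551 genes passed in limma, 1072 higher and 479 lower. The count rested on single libraries. It was 173 without Ep1 1, 826 without Ctrl 2, 856 without Ctrl 4, 943 without Ctrl 1 and 2081 without Ctrl 3, and 695 with no filter on low values.

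In the libraries labelled 20 J/cm2, Ccl4 (mean 7.47 FPKM, n = 2), Cdkn1a (26.9), Hspa1b (23.9), Nptx2 (117) and Hmox1 (23.7) had the largest rises against Ctrl. The 5 genes that fell most by mean were Drd2 (0.724), Gkn3 (0.666), Lrrc10b (2.40), Ttr and the microRNA gene Mir1968. Ttr, the transthyretin gene of the choroid plexus, stood at 16.0 FPKM in Ep1 3 and 172 in Ep1 4, against 543 ± 175 in Ctrl (log2 change -3.27 ± 0.81 SE, limma adjusted p = 0.0273). Its change was -1.59 without Ep1 3 (adjusted p = 0.0606) and -4.94 without Ep1 4, and its call was also lost without Ctrl 1 (adjusted p = 0.0602) or Ctrl 2 (adjusted p = 0.0612). Mir1968, listed at 0 in both libraries, lost its call without any 1 of Ctrl 1, Ctrl 2, Ctrl 4, Ep1 3 and Ep1 4 (largest adjusted p = 0.188). In all 3462 genes passed, 2041 higher and 1421 lower. After rescaling to one total 1576 were higher and 1801 lower, and without mitochondrial genes and CT010467.1 these were 1702 and 2010. Leaving out Ep1 4 gave 660 genes and leaving out Ep1 3 gave 1161, against 4335 without Ctrl 3. More genes passed at this energy than at 10 J/cm2, but a difference between energies needs its own test.

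Tested directly, 20 J/cm2 against 10 J/cm2, 1 gene passed in limma. It was AC149090.1 (ENSMUSG00000095041), named here as the only call after its values were seen. It is annotated as protein-coding on the unplaced scaffold JH584304.1, minus strand, positions 52190 to 59690 in GRCm38. It stood at 133 FPKM at 20 J/cm2, 56.7 at 10 J/cm2 and 64.8 ± 0.774 in Ctrl (log2 difference 1.22 ± 0.08 SE; adjusted p = 0.00302). It has close copies elsewhere in the genome, and the call was lost without Ep1 2, Ep1 3 or Ep1 4. With it, 1019 genes had an unadjusted p under 0.05. Those with the smallest p after it did not pass, among them Alad, with 18.4 FPKM at 10 J/cm2 and 33.2 at 20 J/cm2 (adjusted p = 0.130), Apln with 11.8 and 16.9, Neurod6 with 27.5 and 15.8 and Lrrc10b with 7.67 and 2.40 (adjusted p = 0.321 for each of the last 3).

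As lists, 20 of 39 passed camera between the energies, 17 higher and 3 lower at 20 J/cm2, and none held with an estimated correlation (smallest adjusted p = 0.329 with an estimated correlation, 4 lists at an unadjusted p under 0.05). Choroid plexus and ependyma markers were lower at 20 J/cm2, with a median difference of -0.68 and no member past the threshold over all genes, 6 adjusted over the list alone (camera adjusted p = 5.2e-06, and adjusted p = 0.397 with an estimated correlation). Immediate early genes were higher with a median of 0.32 and glucocorticoid response genes with a median of 0.22, again with 0 members past the threshold over all genes (0 and 1 adjusted over the list alone; adjusted p = 0.467 and 0.329 with an estimated correlation). Without Ep1 2 the median of immediate early genes was 0.0202 (camera adjusted p = 0.352), and without Ep1 4 it was 0.161 (camera adjusted p = 0.0830). The number of lists was 9 without Ep1 2 and 10 without Ep1 4. With 2 libraries per energy, the spread was taken from all 8.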

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

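The tests of a mislabelled Ctrl 3 and of both explanations for AC149090.1 were chosen only after the result was seen. The patterns weighed for striatal genes and Ctrl 3 were themselves noticed in the data. Removal of GC and length trends, and of mitochondrial genes with CT010467.1, was also added after the data were seen. Of the 35 splits of the 8 libraries into 4 and 4, only the real split, 1 in all, called as many genes. It called 3841 and the highest other split called 1. Every other split put Ctrl and Ep1 libraries into the same group, which widened the spread and left few calls possible. The count thus followed the division into Ctrl and Ep1. The splits cannot exclude chance differences between samples or batches that coincide with that division.

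Genes of striatal neurons that express Drd2 were lower in Ep1, and less striatal tissue in the Ep1 samples was weighed as a technical explanation. The 5 indirect-pathway genes (Drd2, Adora2a, Gpr6, Gpr52 and Penk) had a median log2 ratio of FPKM of -2.06, against -0.44 for 10 direct-pathway and pan-striatal genes (exact permutation p = 0.004995, two-sided), but 4 of the 5 had been picked for their large falls, so this test excludes nothing. Penk, the fifth, fell by 1.11, within the range of the second set (-1.42 for Drd1 to 0.13 for Ppp1r1b). Less striatal tissue therefore cannot be told apart from an effect of the treatment, which may contribute and was not tested separately. Removing GC and length trends left 106.3% of the median change of the 5 genes (108.1% of that of the 4 with a known GC content, without Gpr52), which argues against those trends.

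Ctrl 3 stood apart from the other controls, with mitochondrial transcripts at 5.08%, CT010467.1 at 1.46% and the 100 most abundant genes at 18.2% of its fragments. Its mean correlation with them was 0.969 as deposited, 0.968672 without mitochondrial genes and CT010467.1, and 0.974837 after removal of GC and length trends, against at least 0.985 among the other controls under each treatment of the data. Its difference from the other controls followed GC content (Spearman -0.586 over 14496 genes), so these trends may explain part, but not the whole, of the distance. The difference of the Ep1 mean from those controls also followed GC content, less closely (Spearman 0.217). The highest correlation of Ctrl 3 with an Ep1 library was 0.953836, below that of the other controls (at least 0.959), which argues against a swap with an Ep1 sample. A mixture with an outside sample was not tested, and no biological explanation was tested.

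AC149090.1, a gene with pseudogene and parent copies named Pisd, was higher at 20 J/cm2 than at 10 J/cm2 by 1.22 on the log2 scale. Reads moving between copies would leave their sum level, but the lowest sum in the 20 J/cm2 libraries was 608.2 after scaling to library size, against 285.1 to 320.8 elsewhere. A strain or animal variant in copy number cannot be told apart from an effect of the energy label, because the levels coincide with the energies. The lowest 20 J/cm2 library lay 1.96-fold above the highest other library, and libraries within a level differed by at most 1.20-fold. The log2 difference stayed at 1.16, 1.16 and 1.27 without Ep1 2, 3 or 4, which left 1 library at that energy. The call was lost there (adjusted p = 0.0905, 0.0520 and 0.0573), with 0 genes past the threshold in limma (620, 718 and 579 at an unadjusted p under 0.05).

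Single libraries also lay far from the other 3 of their group. Among 286 groups of 4 values, 19 had such a library, and chance gives about 1 in 20 groups, or 14.3 here. Ep1 4 had the fewest fragments, 15038147. Ctrl 3 had 10.4 FPKM of Aldh1l1, 16.7 of Ezr, 62.5 of Gria2, 17.8 of P2ry12 and 15.8 of Tjp1. Ctrl 2 had 3.18 FPKM of Aldh1a2, 41.2 of Ndufs8 and 1.41 of Timp1, and Ctrl 4 had 15.4 of Hbb-bs and 11.6 of Mgp. Ep1 2 had 16.4 FPKM of Cdkn1a, 35.8 of Ezr, 6.01 of Mir1968 and 2.24 of Pmaip1, and Ep1 4 had 1.83 of Csf3r.

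The 2 energies differed by a test of the difference in 20 lists (camera), none with an estimated correlation. Median log2 differences, 20 J/cm2 minus 10 J/cm2, were 0.17 for mechanosensing and shear response, 0.0694 for actin cytoskeleton and 0.10 for the unfolded protein response. They were 0.14 for NF-kB and cytokines, 0.22 for interferon-stimulated genes and 0.17 for MHC class I and antigen presentation. They were 0.32 for immediate early genes, 0.0756 for hypoxia and glycolysis, 0.0731 for lysosome and autophagy, 0.11 for cytosolic ribosomal proteins, 0.0758 for angiogenesis, -0.0570 for synaptic vesicle genes, 0.0796 for circadian clock genes and 0.22 for the glucocorticoid response. Among markers they were 0.19 for endothelial cells, 0.21 for microglia, 0.17 for oligodendrocytes, -0.68 for choroid plexus and ependyma, 0.54 for red blood cells and -0.16 for regions. Many of these rest on single libraries. Without Ep1 2 the difference was 0.0202 for immediate early genes, 0.149 for red blood cells, 0.0621 for NF-kB, 0.000358 for actin, 0.0204 for the unfolded protein response, 0.106 for interferon-stimulated genes, 0.0310 for hypoxia, 0.0273 for circadian genes and 0.12 for microglia, none past the threshold in camera. It was 0.0844 for mechanosensing, 0.121 for endothelial cells and -0.44 for regions, which passed. Without Ep1 4 it was 0.161 for immediate early genes, 0.160 for red blood cells, 0.0546 for NF-kB, 0.114 for angiogenesis and 0.133 for microglia, none past the threshold, and 0.336 for oligodendrocytes. Without Ep1 3 it was 0.0344 for oligodendrocytes, 0.126 for circadian genes and -0.0899 for regions, none past the threshold, and 0.0590 for ribosomal proteins and 0.989 for red blood cells, which passed. Without Ep1 1 it was 0.0155 for regions, not past the threshold. It was larger for some other lists, such as 1.03 for red blood cells and 0.548 for immediate early genes. Lysosome (0.0686), interferon-stimulated (0.180), synaptic vesicle (-0.0405) and oligodendrocyte genes (0.185) also did not pass without Ep1 1. Lysosome genes did not pass without Ep1 2 (0.0635) or Ep1 4 (0.0522), nor did angiogenesis without Ep1 2 (0.0724). Actin (0.0705), the unfolded protein response (0.0685), interferon-stimulated (0.155) and circadian genes (0.0597) did not pass without Ep1 4. Alad, 0.82 higher at 20 J/cm2, and Mir1970, at -1.58, lay on opposite sides of Ctrl at the 2 energies. The difference did not pass in limma for either (adjusted p = 0.130 and 0.318), and the opposite directions were not tested further.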

How the results depend on the processing

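The tests with voom weights, with GC and length trends removed, and without mitochondrial genes and CT010467.1 were chosen only after the result was seen. Between Ep1 and Ctrl, 3841 genes passed. With all 8 libraries it was 2620 (mean FPKM of at least 5) to 4443 (GC and length trends removed), except at 2 stricter thresholds. The count was 239 with an absolute log2 change of at least 1, 1701 at an adjusted p of 0.01 and 1029 with only the 10 J/cm2 samples. The first 2 are stricter thresholds and the third has fewer samples. With only the 20 J/cm2 samples, equal in number, it was 3239, so fewer samples alone do not account for the third count. That contrast is not a test of the energies, between which 1 gene passed directly. The 10 J/cm2 libraries also correlated less with each other (r = 0.983) than the 20 J/cm2 libraries (r = 0.986). Leaving out each library gave 2427 (Ep1 4) to 4141 (Ep1 2). Replicate numbers did not pair the libraries (r from -0.05 to 0.06), and with them as a block 2726 genes and 16 lists passed. Of the 3841 calls, 2386 to 3519 kept call and direction without 1 library, and none changed sign except 1 gene with GC and length trends removed.

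For 10 J/cm2 (1551 genes) the count was 695 with no filter, 166 with the log2 limit and 292 at 0.01, and 173 (without Ep1 1) to 2081 (without Ctrl 3) leaving out each library. For 20 J/cm2 (3462) it was 346 and 1197 at the stricter thresholds, and 660 (without Ep1 4) to 4335 (without Ctrl 3). A group left with 1 library was assumed to vary like the others. Between energies (1 gene) it was 4 with no filter, 2 with GC and length trends removed, 2 with voom and 0 with genes that have a symbol only (923 at an unadjusted p under 0.05), a set without AC149090.1. It was 0 to 1 leaving out each library.

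Of the list calls, 14 between groups and 20 between energies, 0 and 0 were left with an estimated correlation, while fry gave 22 between groups. Leaving out each library gave 13 to 18 and 9 (without Ep1 2) to 21 lists. The region markers' difference between energies (-0.16) reversed to 0.0155 without Ep1 1 and was -0.44 without Ep1 2. Where no reason is given, the cause was not tested. Over single named genes and alternatives, 2608 results kept side and direction, 117 lost and 22 gained a call and 0 reversed, and over lists 827 kept them, 72 lost, 36 gained and 1 reversed. Count-based alternatives planned for a table of counts were not run, because the values are FPKM. Short or low genes such as Mir208a rest on few fragments.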

Other observations

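All tests in this part were chosen only after the result was seen, as were the genes. Among neuropeptide and activity-related genes, Vgf stood at 76.2 ± 15.8 FPKM in Ctrl and 175 ± 33.7 in Ep1 (SD, n = 4 each, limma adjusted p = 0.00282), and Nptx1 at 81.1 ± 5.71 and 150.4 ± 12.1 (limma adjusted p = 0.000233). Scg2 stood at 51.2 ± 1.64 and 81.5 ± 18 (limma adjusted p = 0.00943) and Bdnf at 2.79 ± 0.359 and 5.05 ± 1.79 (limma adjusted p = 0.0355). Penk was lower in Ep1, at 21.9 ± 8.13 against 47.2 ± 3.34 (limma adjusted p = 0.00746). Npy (75.1 and 87.0 FPKM, limma adjusted p = 0.277), Sst (162 and 198, limma adjusted p = 0.0723) and Vip (9.16 and 9.41, limma adjusted p = 0.764) did not pass.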
